A study of Mus musculus with 3 samples.

How the data were processed

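Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where TOX3, a nuclear protein with an HMG-box DNA-binding domain, is found on chromatin of mouse primary hepatocytes. The series holds 3 samples: 2 libraries made with a TOX3 antibody (replicates 1 and 2) and 1 input library made without an antibody. Per the labels' protocols, formaldehyde at 1% was applied for 10 minutes, chromatin was sonicated, and libraries amplified over 15 cycles were sequenced as 150 bp read pairs. The labels do not say whether the replicates came from separate animals or separate cell preparations, so p-values describe these libraries and their spread may be technical.

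The submitters' processing notes name Trim Galore 0.6.4, FastQC 0.11.9, MultiQC 1.8, BWA 0.7.17, MACS2 2.2.6, HOMER and the mouse build GRCm38 (mm10), without stating settings. The authors deposited 1 annotated peak list per ChIP library, so peaks were called per library and not on pooled reads. For each peak the deposited lists give a summit position, a signal value at the summit (its height, whole numbers read here as overlapping fragments), a fold enrichment over background (a linear ratio), the −log10 of the q-value, an annotation class and the nearest gene. These heights, folds and q-values are the authors' own peak values and were used to describe, rank or filter peaks within a list. A column of average signal was not used here. Peak start and end positions, the distance to the transcription start site and a file of the input alone were not used here. Read depth per library is not given in the sources used here.

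The local background behind each fold was recovered from the deposited values as (height + 1)/fold − 1. Its lowest value, the floor, was 0.902 in replicate 1 and 1.04 in replicate 2, and 6.75% and 6.34% of peaks lay at it. Of the recovered values above the floor, 84.5% in replicate 1 and 79.7% in replicate 2 lay within 0.02 of a whole multiple of 1 step, which was 0.506 and 0.564. The step was read as the scaling from input to ChIP depth, which puts replicate 2 at an inferred 1.11 times the depth of replicate 1. Background divided by step is called implied input coverage below. At the 909 peaks whose summits lay within 5 bp in both lists, implied input coverage had a Pearson r of 0.9999 and a Spearman rho of 0.986 across sites, so both lists are treated as called against the same input. That reading rests on the values and not on a statement of the submitters.

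Several planned steps were changed because of what the lists hold. Peaks were counted as shared when their summits lay within 200 bp, a choice listed beforehand as a second option, because the intended overlap of at least 1 bp needs peak ends. For chance levels, summits were placed at random 1000 times between the first and last peak of their chromosome, with a one-sided permutation p whose smallest possible value is 0.000999. A promoter peak is a peak in the authors' promoter class, and its gene is the one they name. The width of that class is not given in the sources used here, and a promoter shared by neighbouring genes counts for 1 of them. Summits of this class can lie kilobases inside the RefSeq gene, so the class does not place a peak at a gene end. A peak within 10 kb names the gene and lies inside its RefSeq span extended by 10 kb. Sequence motifs and GC content were not analysed here, since no genome sequence was used.

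Gene names were matched by symbol, then by a synonym held by 1 gene, to the RefSeq genes of GRCm38.p6 on the main chromosomes (49943 genes, of which 21887 are protein-coding). Of the distinct gene names, 82.8% in replicate 1 and 84.1% in replicate 2 matched, and 92.7% and 94.6% of promoter peaks had a matched gene. As a check of the build, 80.2% and 81.3% of exon and intron peaks lay inside the RefSeq span of the gene named. Gene lists were compared with all other background genes by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 22 lists at a threshold of 0.05. The main background was all 49943 genes. The 23 lists hold 518 distinct genes written from general knowledge, and the TOX family list was described without a test because it has under 5 members.

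The lists, the main tests, most alternatives and the rule for named genes were fixed before the data were examined. The rule names Tox3, Foxo1 and members of both gluconeogenesis lists with a promoter peak in at least 1 library. It then takes up to 4 members of each other list with promoter peaks in both libraries, ranked by the smaller fold. Each gene is described by its promoter peak of highest fold in each library, and a mean with SD is given where those summits lie within 200 bp. That SD leaves out the counting error of the input that both lists are taken to share. Last come the 10 shared peaks with the highest smaller fold, the 10 at protein-coding promoters, the TOX family, and the presence of peaks at G6pc, Pck1, Fbp1 and Pcx. Some genes that meet the rule are not reported here. Shares carry Wilson 95% intervals and summit heights exact Poisson 95% intervals, and both cover counting error only.

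Alternatives were a −log10 q of at least 5, a fold of at least 5, lists of equal length, other backgrounds, and each library alone. Summit windows of 100 and 500 bp, local shifts of 1000 to 20000 bp and the removal of sites of height 100 or more were added after the data were seen. So were the protein-coding background for each library alone, the alternatives for peaks within 10 kb, and 10000 random gene sets matched on gene length in 20 bins.

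The methods were tested on simulated data. A planted overlap of 49.4% between replicate 1 and replicate 2 was recovered as 49.6%. For promoter peaks in both libraries over 21887 protein-coding genes with a base rate of 8.5%, the list test called 38% of lists with a rate of 25% and 91.6% of lists with a rate of 40%. For peaks within 10 kb over 21887 genes, with a hit rate rising with gene length, Fisher's exact test called 35.7% of unchanged lists of long genes at an unadjusted 0.05. Length-matched sets called 2.33% of those lists, and 87% of lists whose rate was raised by 30 percentage points. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.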

Results

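TOX3 binding was profiled in mouse primary hepatocytes, the liver cells that make glucose, with 2 ChIP libraries and 1 input library. The series title places TOX3 upstream of the forkhead transcription factor FoxO1 in hepatic glucose production, so the peak lists address where TOX3 lies relative to Foxo1 and to genes of gluconeogenesis. Replicate 1 had 16871 peaks, which named 11515 genes, and replicate 2 had 31977 peaks, which named 18396 genes. The median summit height was 19 fragments in replicate 1 and 22 in replicate 2, and the median fold enrichment was 4.81 and 4.83. Median −log10 q was 6.34 and 7.55. The inferred depths differed 1.11-fold, while the numbers of peaks differed 1.90-fold.

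At Foxo1, a gene on chromosome 3 (52268337 to 52350109, GRCm38) whose product activates gluconeogenic genes and is held out of the nucleus by insulin signalling, both libraries had a promoter peak. The summits lay at 52267810 in replicate 1 and 52267788 in replicate 2, which is 527 and 549 bp outside the RefSeq gene. Summit height was 22 fragments (95% interval 13.8 to 33.3) over a local background of 4.05 in replicate 1, and 23 fragments (14.6 to 34.5) over 3.95 in replicate 2. Fold enrichment at this promoter was 4.70 ± 0.21 (SD, n = 2), close to the median peak of each list. Its −log10 q was 6.81 and 8.08. Replicate 2 had a further intergenic peak named for Foxo1 at 52258002, with a height of 12 fragments and a fold of 6.11, and replicate 1 had none within 200 bp of it.

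At 4 key enzymes of gluconeogenesis, no promoter peak was found in both libraries. No peak in either list named G6pc, the glucose-6-phosphatase that releases free glucose, or Fbp1, fructose-1,6-bisphosphatase. Pck1, the cytosolic phosphoenolpyruvate carboxykinase on chromosome 2 (173153073 to 173159274), was named by 2 peaks in replicate 1 and 3 in replicate 2. None was in the promoter class, and none lay within 200 bp of a peak in the other list, although the termination-site peaks at 173155198 and 173154843 were 355 bp apart and would be shared at 500 bp. The strongest was at 173154843 in replicate 2, inside the gene and annotated to a transcription termination site, with 21 fragments (13 to 32.1) and a fold of 10.8. Its local background of 1.04 was the floor of that list. Both termination-site summits of Pck1 lay inside the gene, nearer the lower than the upper coordinate of its span. That class therefore does not place them at a gene end. Pcx, pyruvate carboxylase on chromosome 19 (4510472 to 4621752), had a termination-site peak near its 3' part in both lists, at 4602616 with a fold of 5.34 and at 4602650 with a fold of 4.24. Another shared Pcx peak lay at 4604478 with a fold of 4.46 in replicate 1 and at 4604509 with a fold of 4.11 in replicate 2. A Pcx promoter peak at 4510696, with a fold of 5.11, was listed in replicate 2 alone. The lists hold peaks above a threshold only, so a gene without a peak was not detected at this depth.

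**Figure D1:**
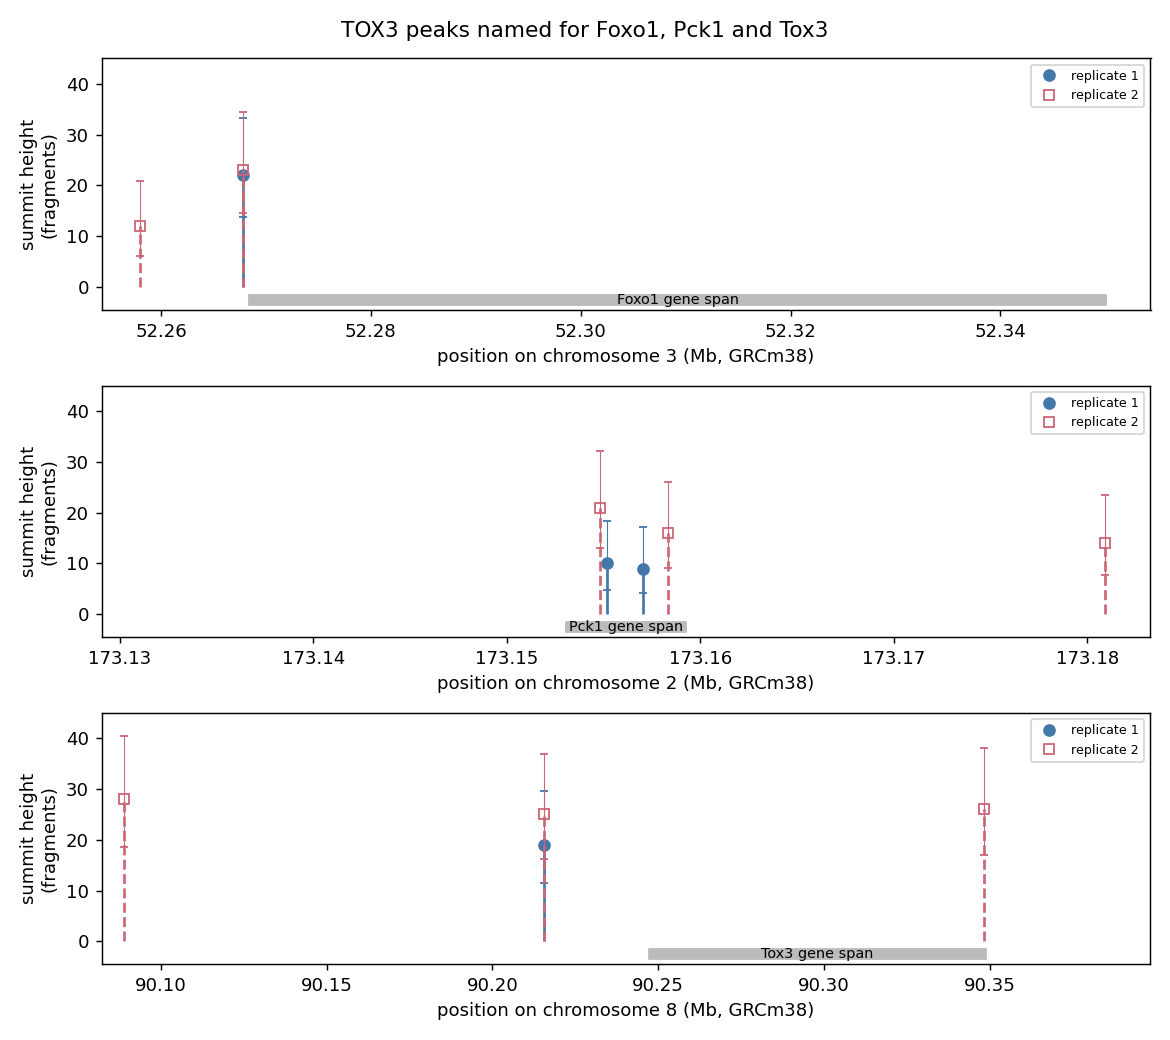
Summit height in fragments (y axis) against position in Mb on GRCm38 (x axis) for peaks named for Foxo1, Pck1 and Tox3, with filled circles for replicate 1, open squares for replicate 2, vertical bars for exact Poisson 95% intervals and grey bars for gene spans. Both libraries have a summit at the Foxo1 promoter, with heights of 22 and 23 fragments, whereas the nearest Pck1 summits of the libraries lie 355 bp apart.

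Among 24 gluconeogenic enzymes and transporters, 2 had a promoter peak in replicate 1, 14 in replicate 2 and 2 in both. The genes in both were Slc25a10, the mitochondrial dicarboxylate carrier, with a fold of 6.80 ± 0.74 (SD, n = 2), and Tpi1, triosephosphate isomerase, with 6.96 ± 2.5 (SD, n = 2). The Slc25a10 summits lay inside the gene, 3749 and 3743 bp from its nearer end, and the Tpi1 summits 435 and 277 bp from theirs. Promoter peaks in replicate 2 alone were at Eno1, G6pc3, Got1, Gpi1, Mdh1, Mpc1, Mpc2, Pck2, Pcx, Pgam1, Pgk1 and Slc25a11. The highest fold among the list's promoter peaks in replicate 2 was 9.67 at Pck2, the mitochondrial phosphoenolpyruvate carboxykinase, and the lowest was 3.27 at Mdh1, cytosolic malate dehydrogenase. The Pck2 summit lay inside the gene, 3427 bp from its nearer end. By two-sided Fisher's exact test over all genes, promoter peaks in both libraries gave an odds ratio of 2.05 for this list with an adjusted p = 0.528. The odds ratio was 0.974 against protein-coding genes and 0.825 against genes named in either list, so its direction turned with the background. By the same exact test over all genes it was 8.58 without replicate 1 (adjusted p = 4.118e-06) and 1.55 without replicate 2 (adjusted p = 0.586).

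Among 30 regulators of gluconeogenesis, 3 had a promoter peak in replicate 1, 14 in replicate 2 and 3 in both. The genes in both were Foxo1, the nuclear receptor Nr4a2 and Stk11, the kinase LKB1 that activates AMPK. The strongest promoter summits lay 22 bp apart at Foxo1, 1264 bp apart at Nr4a2 and 9583 bp apart at Stk11. A weaker pair of Nr4a2 summits lay 175 bp apart. The strongest Nr4a2 summits were 7863 and 8046 bp inside the gene from its nearer end. Those of Stk11 were 5302 bp from the nearer end in replicate 1 and 27 bp in replicate 2. Peaks in replicate 2 alone were in the promoter class at Cebpb, Creb1, Crebbp, Crtc2, Gcgr, Nr3c1, Nr4a1, Ppargc1b, Prkaa1, Prkar1a and Sik1. The Nr3c1 and Nr4a1 summits lay inside the gene, 30282 and 7990 bp from its nearer end. Folds in replicate 2 ran from 2.31 at Ppargc1b to 8.60 at Prkaa1, a catalytic subunit of AMPK. The odds ratio for promoter peaks in both libraries was 2.5 over all genes (two-sided Fisher's exact test, adjusted p = 0.294). It was 1.19 against protein-coding genes and 0.841 against genes named in either list. By the same exact test over all genes it was 5.36 without replicate 1 (adjusted p = 5.684e-05) and 1.89 without replicate 2 (adjusted p = 0.461). Over protein-coding genes, replicate 2 alone gave 2.22 (exact test, adjusted p = 0.0974).

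Genes of insulin signalling had promoter peaks in 4 of 30 members in replicate 1, 18 in replicate 2 and 3 in both, including Pik3r2 and Rptor. Fold was 3.36 ± 0.35 (SD, n = 2) at Rptor, the raptor subunit of mTOR complex 1. Of 28 reported FoxO target genes, 2, 13 and 1 had such peaks, and the gene in both was Trib1, with folds of 4.14 and 2.41 at summits 1105 bp apart. The odds ratio for both libraries was 2.5 for insulin signalling and 0.834 for FoxO targets, with adjusted p = 0.294 and 1 by two-sided Fisher's exact test over all genes. Against protein-coding genes the odds ratios were 1.19 and 0.397, and against genes named in either list 0.876 and 0.334.

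In other metabolic lists, promoter peaks in both libraries were found at 5 of 28 glycolysis and glycogen genes, 2 of 25 genes of fatty acid oxidation and 1 of 24 genes of bile acid and xenobiotic metabolism. In the glycolysis and glycogen list, the genes with the highest smaller folds were Phkg2, a subunit of phosphorylase kinase, and hexokinase 2 (Hk2), followed by Pfkp and Mlxipl. The strongest promoter peak of Phkg2 had a fold of 6.75 in replicate 1 and 8.91 in replicate 2, and that of Hk2 had 5.94 and 7.61, at summits 4043 and 724 bp apart. A nearer pair of Phkg2 promoter summits lay 59 bp apart. Etfb and Bdh1, a ketone body dehydrogenase, represented fatty acid oxidation, and Por, the electron donor of cytochromes P450, represented xenobiotic metabolism. The nearest promoter summits of the libraries lay 147 bp apart at Etfb, 708 bp at Bdh1 and 1002 bp at Por. No gene of lipogenesis (24), cholesterol synthesis (23), the urea cycle and amino acid breakdown (26) or hepatocyte secreted proteins (28) had a promoter peak in both libraries. Replicate 2 had them at 10, 11, 6 and 3 of these genes. Since 4.25% of other genes had a promoter peak in both libraries, lists of this size are expected to hold few. The adjusted p was 0.731 for each of these 4 lists (two-sided Fisher's exact test over all genes). The glycolysis list had an odds ratio of 4.91 and an adjusted p = 0.0659 by two-sided Fisher's exact test over all genes. Against protein-coding genes the exact test gave 2.33 and an adjusted p = 0.461.

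Of lists of general cell function, 4 of 22 clock genes (Tef, Csnk1e, Hlf and Rora), 4 of 32 ribosomal protein genes, 4 of 28 cell cycle genes and 2 of 30 respiratory chain genes had promoter peaks in both libraries. Cdc20, an activator of the anaphase-promoting complex, had a fold of 6.30 ± 2.5 (SD, n = 2), and Ccnd1, cyclin D1, had 4.41 ± 0.33 (SD, n = 2). Rpl18, Rps18, Rps24 and Rpl12 were the ribosomal genes, and the respiratory chain genes included Cox7c. None of 26 immediate early and stress response genes had a promoter peak in both, against 14 in replicate 2. For peaks in both, the two-sided Fisher's exact test gave an adjusted p = 0.731 over all genes and 0.461 over protein-coding genes. Gata6 was the 1 of 22 hepatocyte transcription factors with promoter peaks in both libraries. Odds ratios over all genes were 5.01 for clock, 3.22 for ribosomal and 3.76 for cell cycle genes (two-sided Fisher's exact tests, adjusted p = 0.0709, 0.143 and 0.108). Against protein-coding genes they were 2.38, 1.53 and 1.79.

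Among markers of cells outside the hepatocyte lineage, promoter peaks in both libraries were found at 6 of 20 neuronal genes, 3 of 15 stellate, 2 of 15 endothelial, 3 of 12 cholangiocyte and none of 16 Kupffer cell genes. The neuronal genes included Neurod1, a transcription factor of neuronal differentiation, with 9.10 ± 0.98 (SD, n = 2). Its local background was the floor of each list, 0.902 and 1.04. Next by the smaller fold came Rbfox3, with summits far apart at 118569586 and 118909204 on chromosome 11, then Gad1, which makes the transmitter GABA, and Slc17a7. The strongest Gad1 promoter peaks had folds of 5.70 and 11.8 at summits 213 bp apart, and a nearer pair lay 21 bp apart. Krt7, a keratin of bile duct cells, had 7.38 and 6.89 at summits 205 bp apart, with Slc4a2 and Cftr also in the list. Ngfr, Reln and Des were the stellate genes, and Stab1 and Eng the endothelial ones. The neuronal list was the 1 of 22 lists past the threshold (odds ratio 9.68, adjusted p = 0.00298, two-sided Fisher's exact test). The odds ratio was 4.08 without replicate 1 and 9.19 without replicate 2, and over protein-coding genes 1.69 and 4.46. By the same exact test against protein-coding genes alone, its odds ratio was 4.60 with an adjusted p = 0.115, so the call was not kept, nor was it against genes named in either list (adjusted p = 0.301).

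The libraries gave different counts of lists. Over all genes, 17 lists passed the same test in replicate 2 alone and 5 in replicate 1 alone. Over protein-coding genes, 6 passed in replicate 2 alone and 0 in replicate 1 alone. The 6 were higher for gluconeogenic enzymes (odds ratio 3.55, adjusted p = 0.0227), insulin signalling (3.81, adjusted p = 0.00721), clock (3.67), ribosomal (2.88) and immediate early genes (2.96), and lower for Kupffer cell markers, with 0 of 16 genes (two-sided Fisher's exact tests). The protein-coding comparisons of single libraries were chosen after the data were seen, and the difference between libraries in these lists was not tested.

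**Figure D2:**
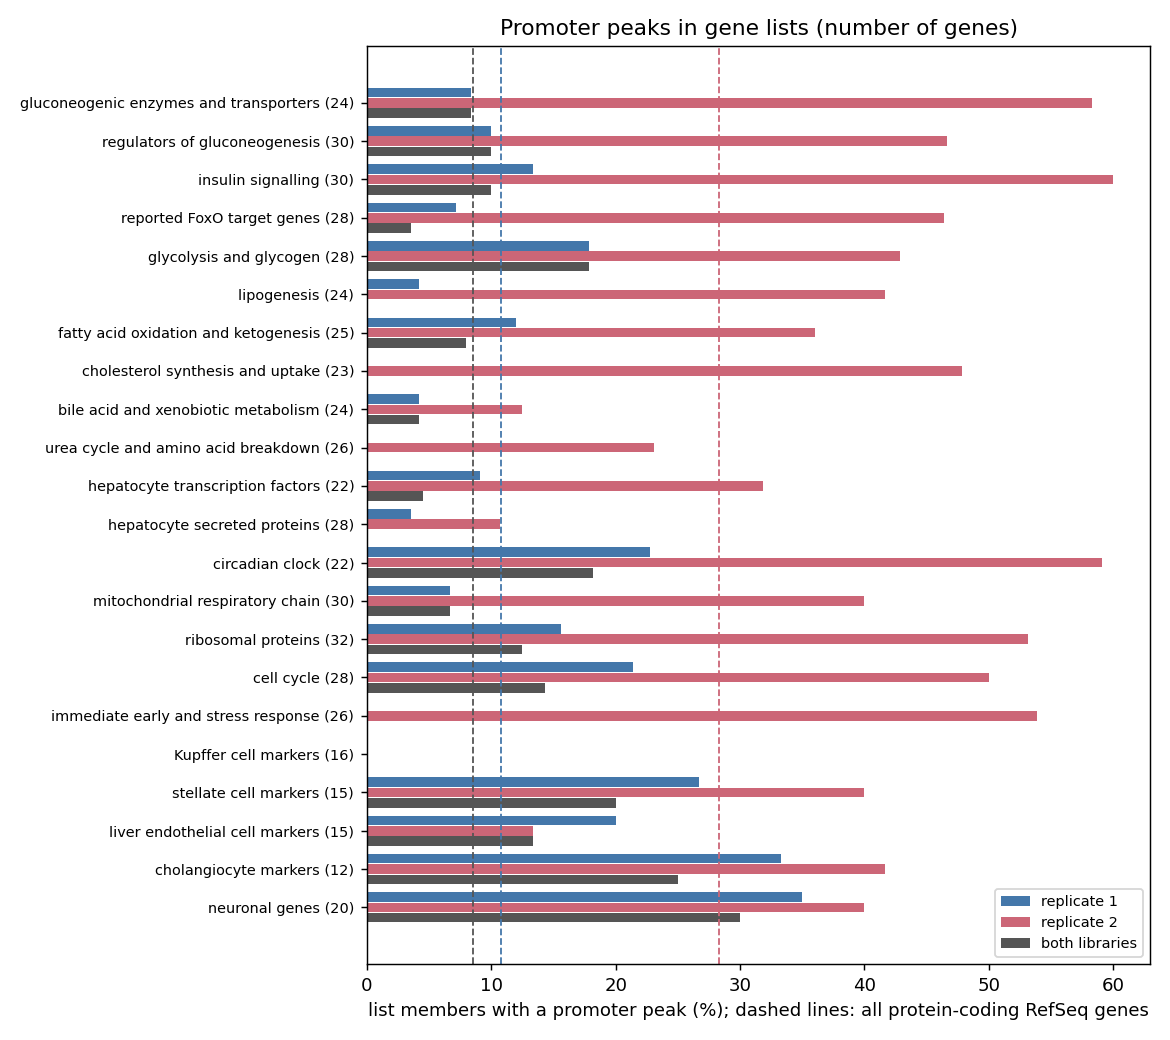
Percentage of members of each gene list with a promoter peak (x axis) for replicate 1, replicate 2 and both libraries, with list sizes in parentheses and dashed lines for all protein-coding genes in the same colours. Replicate 2 covers 14 of 24 gluconeogenic enzymes and transporters, against 2 in both libraries, and 6 of 20 neuronal genes carry a promoter peak in both.

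Peaks anywhere in or within 10 kb of a gene were found in both libraries at 16 of 30 regulators of gluconeogenesis, 13 of 30 insulin signalling genes and 7 of 24 gluconeogenic enzymes and transporters. Cholangiocyte markers had such peaks at 8 of 12 genes and neuronal genes at 10 of 20. Over all genes, 11 of 22 lists passed the two-sided Fisher's exact test, with an odds ratio of 7.30 and an adjusted p = 6.177e-06 for the regulators. Without replicate 1 this odds ratio was 37.5, with peaks at 28 of 30 regulators, and without replicate 2 it was 6.05. Over protein-coding genes 2 lists passed the exact test, the regulators (odds ratio 3.21, adjusted p = 0.0343) and the cholangiocyte markers (5.62, adjusted p = 0.0429). The regulators had a median length of 34.4 kb and the cholangiocyte markers 15.3 kb, against 17.2 kb for all protein-coding genes. Against random gene sets matched on length, 0 of 22 lists passed after adjustment, and 3 had an unadjusted permutation p under 0.05. The regulators had 16 genes against 8.78 expected (permutation p = 0.0108, adjusted p = 0.163), and the cholangiocyte markers 8 against 3.46 (permutation p = 0.0148, adjusted p = 0.163). The respiratory chain went the other way, with 2 genes against 7.32 expected (permutation p = 0.0238, adjusted p = 0.175).

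Across the genome, 8690 peaks were shared, which was 51.5% (50.8 to 52.3) of replicate 1 and 27.2% (26.7 to 27.7) of replicate 2. Shared summits lay a median of 43 bp apart. Random placement gave 0.595% and 0.314%, and the permutation p was 0.000999 for each list, the smallest the placements allow. Shifting peaks locally gave 2.21% and 1.17%. In libraries simulated without enrichment against the same input at 31977 sites, 4.92% of replicate 1's few calls were also called in replicate 2. That simulation made a mean of 39.0 and 42.3 calls per library. It therefore cannot give the sharing that a common input would produce at the real numbers of peaks. With replicate 2 shortened to 16871 peaks by rank, 33.1% of each list was shared.

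Peaks with a higher −log10 q were found more often in the other library. From the lowest to the highest quintile of −log10 q, the shared percentage went from 45.5% to 59.6% in replicate 1 and from 17.9% to 40.3% in replicate 2. Ranked by fold, the quintiles of replicate 1 showed no steady rise (52.6%, 51.2%, 49.3%, 49.2% and 55.3%), while replicate 2 went from 19.4% to 34.1%. Across the 8690 shared peaks, which are not independent replicates, fold enrichment had a Spearman rho of 0.68 between libraries. With implied input coverage removed, rho was 0.21, and for −log10 q it was 0.37.

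**Figure D3:**
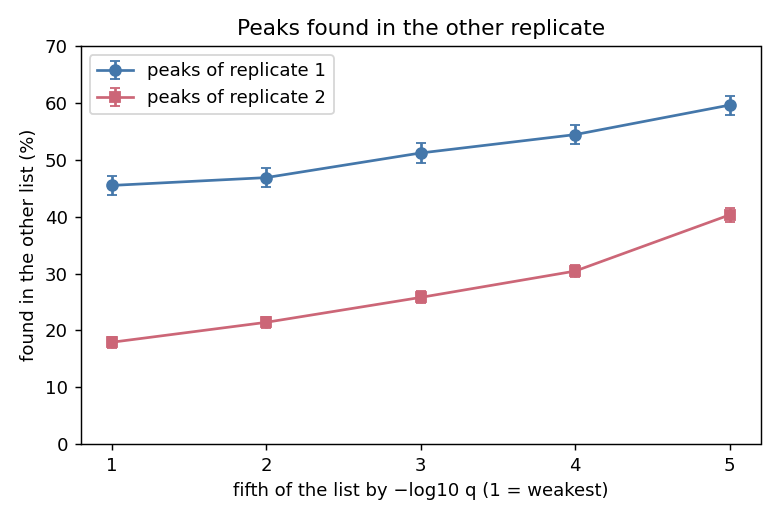
Percentage of peaks with a summit within 200 bp in the other list (y axis) by quintile of −log10 q within each list (x axis, weakest first), with Wilson 95% intervals. The shared percentage reaches 59.6% in replicate 1 and 40.3% in replicate 2 among the strongest peaks.

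Promoters held 19.7% (19.1 to 20.3) of peaks in replicate 1 and 26.9% (26.4 to 27.4) in replicate 2. Exons held 22.8% and 20%, introns 25.1% and 25.2%, termination sites 11.1% and 9.58%, and intergenic sequence 21.3% and 18.3%. In replicate 1 the promoter percentage was higher in shared peaks than in the others (20.8% against 18.5%, odds ratio 1.15, two-sided Fisher's exact test p = 2.515e-04). In replicate 2 it was lower in shared peaks (21.7% against 28.8%, odds ratio 0.686, two-sided Fisher's exact test p = 7.242e-38). Peaks of low fold were more often at promoters. In replicate 2, promoters made up 44.3% of the peaks in the lowest quintile of fold and 14.8% of those in the highest, and in replicate 1 they made up 27.9% and 14.1%. Promoter summits were not low in height, with medians of 22 fragments in replicate 1 and 27 in replicate 2. Exons, the next class, had 21 and 24. Median implied input coverage, which sets the background under the fold, was also highest at promoters. It was 8 and 11 there, against 7 and 7.78 at exons.

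**Figure D4:**
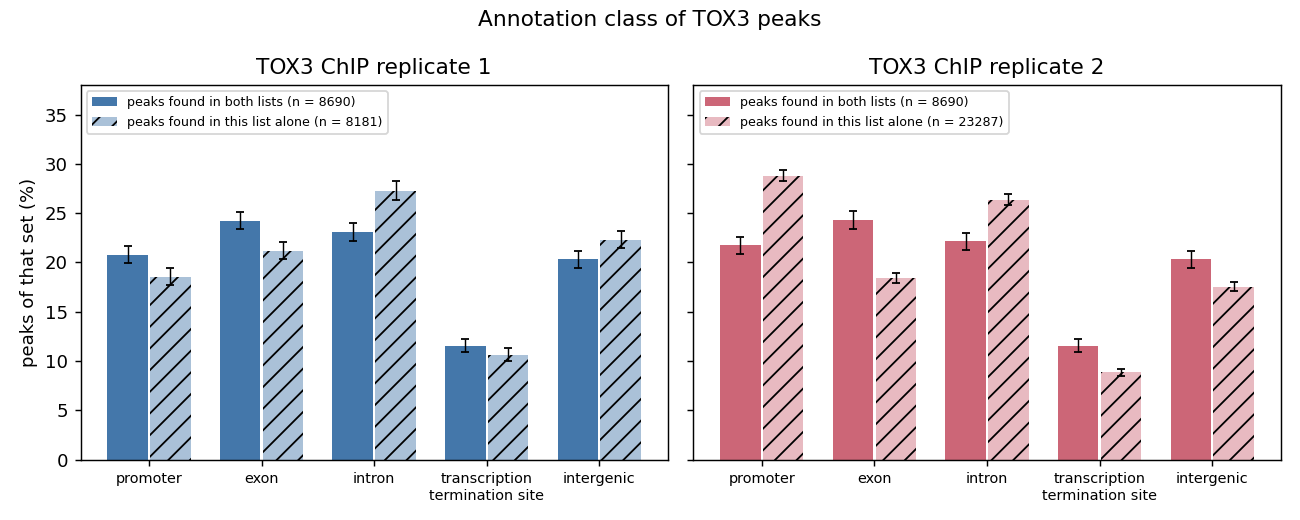
Percentage of peaks in each annotation class (y axis) for peaks found in both lists (plain bars) and in 1 list (hatched bars), with Wilson 95% intervals, for each replicate. Promoters hold 28.8% of the peaks found in replicate 2 alone, against 21.7% of its shared peaks.

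At the level of genes, 2770 had a promoter peak in replicate 1, 7019 in replicate 2 and 2123 in both, against 389 expected from independent lists over 49943 genes. Over 21887 protein-coding genes 1868 were in both against 668 expected, and over the 17009 genes named in either list the expectation was 1143. The odds ratios were 28.3, 13.3 and 6.26 (two-sided Fisher's exact tests, p below the range the software can hold). Requiring a −log10 q of at least 5 left 1357 genes in both. Of the 2123 genes, 1433 (67.5%) had promoter summits within 200 bp of each other.

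The shared peaks with the highest smaller fold lay largely away from promoters, with 6 of 10 intergenic, 3 in introns and 1 at a promoter. The first, at 47682321 on chromosome 6 and named for Gm25283, had 43 fragments and a fold of 17.5 in replicate 1, and 68 fragments and a fold of 25.6 in replicate 2. A neighbouring peak at 47673643 and one at 47749782, named for the small RNA gene Rny3, were also among the 10. Others were named for Gm21112, Rb1cc1, a scaffold protein of autophagy initiation, Gm20586, Cwc25, Mir5624 and Slc8a2. The promoter peak was at Nup85, a nuclear pore component on chromosome 11, with a summit at 115570126 and a fold of 11.7 ± 0.13 (SD, n = 2). After Nup85, the highest peaks of the promoter class at protein-coding genes were Celf4, Bicdl2, Lhx3, Stat3, Sipa1l1, Cntn4, Krt80, Mcrs1 and Dgkz. Some lay close to a gene end, as at Celf4 (summit 25754380, span 25477620 to 25754520). Others lay well inside the gene, as at Stat3 (summit 100905798, span 100886806 to 100939594) and Sipa1l1 (summit 82310919, span 82169377 to 82451786). Stat3, which carries interleukin-6 signals in liver, had 9.67 ± 0.38 (SD, n = 2). These ranks describe peaks within the lists and carry no test. High folds went with low backgrounds. In the highest quintile of fold, median implied input coverage was 3 in replicate 1 and 2.85 in replicate 2, against 12 and 15 in the lowest.

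Tox3 itself, on chromosome 8 (90247110 to 90349029), had an intergenic peak in both libraries at 90215538 and 90215607, 31572 and 31503 bp outside the gene. Its fold was 9.94 in replicate 1 and 12.7 in replicate 2, with 19 (11.4 to 29.7) and 25 (16.2 to 36.9) fragments. A Tox3 promoter peak with a fold of 4.07 was listed in replicate 2 alone. Of the other TOX family genes, Tox2 was named by 3 and 7 peaks, with promoter peaks in replicate 2 alone, and no peak named Tox or Tox4. Tox2 peaks outside the promoter class at 163323043 and 163339617 in replicate 1 were shared, with replicate 2 summits 37 and 128 bp away.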

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

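The tests on protein-coding genes for single libraries or for at least 1 library, all alternatives for peaks within 10 kb, and the removal of input coverage were chosen after the data were seen. The shared percentage stayed above random placement in both lists under every alternative run, from 33.1% to 61.7% in replicate 1 and from 21.4% to 33.1% in replicate 2. Peaks with a fold of at least 5 numbered 7639 and 14769. Agreement of peak strength was 0.37 with −log10 q and 0.21 with input coverage removed, and the cause of the first drop was not tested. At a −log10 q of at least 5, 1357 genes had promoter peaks in both libraries, as fewer peaks were kept, and replicate 2's promoter percentage was 26.1%, for which the cause was not tested. With 1 library left out, a peak in the other was enough, and genes with a promoter peak numbered 2770 in replicate 1 and 7019 in replicate 2. Lists past the threshold over all genes then numbered 5 and 17, and the cause of these list counts was not tested.

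Lists with promoter peaks past the threshold numbered 0 against genes named in either list and 0 against protein-coding genes. With protein-coding genes there were 6 in replicate 2 alone, 0 in replicate 1 alone and 6 for a peak in at least 1 library. For peaks within 10 kb there were 7 at the stricter q, 18 without replicate 1, 13 without replicate 2, 2 with protein-coding genes and 0 with length-matched sets.

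Some odds ratios changed side of 1, mostly without a call in either setting. At the stricter q, bile acid and xenobiotic genes were at 1.56. With 1 library left out, odds ratios ran from 1.31 to 5.31 for FoxO targets, 0.740 to 4.37 for lipogenesis and 0.941 to 4.26 for endothelial genes. Without replicate 1 they were 5.61 for cholesterol, 1.84 for urea cycle and 7.15 for immediate early genes, and without replicate 2 each of these was 0. Against genes named in either list, gluconeogenic enzymes were at 0.825, regulators 0.841, insulin signalling 0.876, fatty acid oxidation 0.876, bile acid genes 1.40 and hepatocyte factors 0.389. Against protein-coding genes, gluconeogenic enzymes were at 0.974, fatty acid oxidation 0.932, hepatocyte factors 0.510 and respiratory chain 0.765. There, replicate 2 alone gave 2.2 for FoxO targets, 1.81 for lipogenesis, 2.32 for cholesterol, 2.96 for immediate early and 0.390 for endothelial genes. Replicate 1 alone gave 0.752 for gluconeogenic enzymes, 0.919 for regulators, 0.827 for hepatocyte factors and 0.590 for respiratory chain. A peak in at least 1 library gave 2.28, 1.92, 2.09, 2.66 and 0.568 for FoxO targets, lipogenesis, cholesterol, immediate early and endothelial genes. Within 10 kb the stricter q gave 1.33 for bile acid genes, 0.619 for ribosomal, 0.773 for immediate early and 1.33 for Kupffer genes. With 1 library left out it ran from 0.634 to 1.73 for secreted proteins, 0.377 to 2.34 for respiratory chain and 0.755 to 1.22 for Kupffer genes, and with protein-coding genes 0.841 for urea cycle, 0.785 for ribosomal and 0.841 for immediate early genes. The cause was not tested beyond the number of peaks and the background used.

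Overlap by a share of peak length, promoter windows of 500, 1000 and 5000 bp, and motif and GC settings were not run. Depth limits the calls of single genes, since typical summits hold about 19 to 22 fragments.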

Other observations

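The gene family scan and the tests of input dips (pooled and by class), tall sites, input coverage at promoters and gene number on X were chosen after the results were seen, while those of depth and of the X copy number were chosen before. Families of at least 20 protein-coding genes whose symbols start alike, 102 in all, were compared with all other protein-coding genes by two-sided Fisher's exact tests. Promoter peaks in both libraries were absent from 1110 olfactory receptor genes (Olfr, exact test, adjusted p = 1.126e-42) and 355 vomeronasal receptor genes (Vmn, adjusted p = 1.424e-12). Zinc finger genes (Zfp) had them at 13 of 397 (exact test, odds ratio 0.358, adjusted p = 0.00129), and no family was higher. In replicate 2 alone 14 families were higher, among them Arhgef guanine nucleotide exchange factors at 16 of 25 (exact test, odds ratio 4.51, adjusted p = 0.00169) and Eif translation factors at 28 of 56 (2.54, adjusted p = 0.00438). The same library was lower in 25 families, including cytochromes P450 (Cyp) at 12 of 99 (exact test, odds ratio 0.348, adjusted p = 0.00157) and major urinary protein genes (Mup) at 0 of 24. In replicate 1, 2 families were higher, fibroblast growth factors (Fgf) at 8 of 22 and collagens (Col) at 12 of 44 (exact tests, odds ratios 4.74 and 3.11, adjusted p = 0.0367 and 0.0384). In replicate 2, where promoter peaks were more common, these families had 8 and 14 genes with exact test odds ratios of 1.45 and 1.18 (adjusted p = 0.616 and 0.743), and the difference between libraries was not tested.

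The tallest shared sites had low folds. At Gm10800 on chromosome 2, the summit at 98667144 held 35044 fragments in replicate 1 and 35858 in replicate 2, with folds of 1.21 and 1.09. Gm10722 and Gm10718 on chromosome 9 followed, with 11660 and 8046 fragments in replicate 1.

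Sharing of peaks beyond random placement could arise from dips in the common input or from tall sites called in any library. Sites of height 100 or more or off the main chromosomes were 81 of replicate 1's 16871 peaks and 67 of its 8690 shared ones, too few to be the main source (51.3% shared without them). Implied input coverage at shared over single peaks had a ratio of medians of 1.24 (bootstrap 95% interval 1.07 to 1.40) in replicate 1 and 1.04 (1 to 1.12) in replicate 2. Outside promoters it was 1.2 in both, and the ratio of geometric means was 1.18 (1.15 to 1.21) and 1.14 (1.12 to 1.17), where dips predicted ratios below 1. At equal fold, a site of higher coverage holds more fragments and passes more easily in both lists, so these ratios cannot exclude dips. At promoters the ratio of medians was 1 (0.914 to 1.09) and 0.771 (0.674 to 0.818), and that of geometric means 1.07 (1.02 to 1.12) and 0.835 (0.805 to 0.867), so the libraries point apart. Input dips stay open in both classes. The most shared quintile of −log10 q, a measure computed from the background, had a median coverage of 4.75 against 9 in the least shared of replicate 1. By fold, also computed from the background, the most shared quintile had 3 in replicate 1 and 2.85 in replicate 2, against 4 and 15 in the least shared. Enrichment that does not depend on TOX3 stays open, since no control antibody was analysed here, and no biological explanation was tested for this sharing.

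Replicate 2 had 6706 promoter peaks with no summit of replicate 1 within 200 bp. Lower depth of replicate 1 would leave them below its weakest listed evidence, yet 94.2% (93.6 to 94.7) would pass at the height the inferred depth ratio predicts, and 85.5% when heights were redrawn with counting noise. Heights selected for passing in replicate 2 are biased upward, which was not corrected. Implied input coverage was 1.30 times higher (1.22 to 1.48) at these promoters than at shared ones, with medians of 11.7 and 9. This is the inverse of the ratio of 0.771 given above for input dips, so accessible chromatin carried into replicate 2 as into the input and dips at shared promoters cannot be told apart by it, and weaker enrichment of the antibody in replicate 1 was not tested.

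The X chromosome held 184 peaks (1.09%) in replicate 1 and 330 (1.03%) in replicate 2, against 5.03% of RefSeq genes. Gene number does not account for this, as peaks per 100 genes on X were 0.310 times those of the lowest autosome in replicate 1 and 0.294 in replicate 2. With 1 copy of X per cell, input coverage at intergenic and intron peaks might be lower there, and its ratio to autosomes was 0.5999 (0.4 to 0.706) in replicate 1 and 0.674 (0.6 to 0.833) in replicate 2. The intervals span the value of 0.65 set for this test, so the X copy number stays open. The sex of the animals is not in the labels, and the Y chromosome held 17 and 20 peaks, of which 9 and 10 lay beyond 90 Mb and 3 of the others were shared, but reads from repeated sequence were not told apart there.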
